A study of Homo sapiens with 99 samples.

How the data were processed

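The study measured RNA in HEK293T cells by sequencing of total RNA, in 99 samples that form 33 groups of 3 replicates. Per the labels' protocols, RNA was extracted with RNeasy columns, and an outside company made and sequenced the libraries. Per the labels' processing notes, the authors used fastp 0.23.2, STAR 2.7.5b, Picard 1.2, RSEM 1.3.3 and DESeq with the hg38 genome. The roles of Picard and DESeq and the gene annotation were not stated. The deposited tables, 1 for ZBTB3 and 1 for ZBTB9, hold expected counts per gene as estimated by RSEM, with 51 libraries each, the 3 parental libraries being in both (102 count columns in all). The deposited sample sheets were read for the meaning of column names and were not used as data.

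Groups were taken from the sample titles. For the ZBTB3 WT, K116A and ZBTB9 WT lines the titles of the DMSO controls for 24 h give no time, and their column names give 24 h. Other fields disagreed with some titles. The treatment field says DMSO for the doxycycline samples of the ZBTB9 WT and W128A lines, and the time field says 24 h for the ZBTB3 knockout samples titled 48 h. The sample sheets give 0 h and no treatment for the knockout libraries titled DMSO for 24 h, the controls of the knockout and 24 h doxycycline contrasts, whose column names hold neither DMSO nor a time. The ZBTB3 sheet repeats the 24 h sample names for the WT DMSO 48 h libraries. The titles were used, matched to the columns through the sample names in the labels. The series text names the ZBTB3 mutant K166A once where the samples say K116A, and the sample name is used here. The doxycycline doses for 24 h were 0.01, 0.1 or 1 ug/mL, and for 48 h 1 ug/mL.

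Expected counts were rounded to whole numbers. Genes passed filterByExpr (at least 10 counts scaled to the median library in 3 libraries, and 15 in total), which kept 16160 of 27357 genes for ZBTB3 and 16961 of 26695 for ZBTB9. Libraries were scaled by TMM, and edgeR 4.0.16 fitted 1 quasi-likelihood model with a mean per group to the 51 libraries of each table. Each of 32 comparisons was a contrast of that model, with p-values adjusted by the method of Benjamini and Hochberg over the genes tested and called under 0.05. The comparisons were knockout against parental cells, doxycycline in knockout cells without transgene, doxycycline in each transgene line, the difference between the WT and mutant inductions, and the mutant against the WT line with DMSO. Gene lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01, and again with a correlation estimated from the data and with fry. Calls for list members were also adjusted over the list alone. The lists were mitochondrially encoded OXPHOS, ATF4 and amino acid stress, unfolded protein, heat shock, glycolysis and hypoxia, cholesterol synthesis, S phase, G2 and M phase, p53 targets, interferon, immediate early, Wnt, TGF-beta and matrix, Notch, germline, neuronal, the ZBTB family, corepressors, ribosomal proteins and nuclear OXPHOS, with 4 lists of cell type markers (epithelial, fibroblast, blood and liver). Groups, comparisons, lists and the first set of alternatives were fixed before the data were examined.

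In each comparison ZBTB3 and ZBTB9 were looked up, then the 12 largest positive and 12 largest negative log2 fold changes among called genes with a mean of at least 1 CPM in either group and no overlap between groups. Members of the fixed lists were looked up as well. The text names examples from these, mostly genes that kept their call in the alternatives, and gives the exceptions. Log CPM used a prior count of 2. A fold against a group without counts was computed against a floor of 3 counts over the group, and it covers counting error alone. Agreement between responses was the Pearson correlation of log2 fold changes between comparisons without a common library, and shared genes were set against the number expected from the 2 counts. Reversal was the share of knockout genes, called and changed by at least 2-fold, that moved the opposite way on induction.

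The alternatives were RLE size factors, no expression filter, DESeq2 1.42.0, a fit of only the groups compared, a block for replicate number with terms shared by all groups of the fit, and each library left out in turn. After the results were seen, 3 more were added. They were a correction for GC content and length (a spline with 5 degrees of freedom per library, fitted to genes with a mean log2 CPM above 2), a block for replicate number within the 24 h doxycycline groups, and the omission of their replicate 2 for ZBTB9. GC content and length came from GENCODE release 29 for 21963 of 27357 genes by symbol, and 25567 symbols were found in RefSeq. Replicate numbers were taken as pairs where each of the 3 same-number correlations passed 0.1. This held for 1 induction, ZBTB3 K116A at 48 h (0.19, 0.17 and 0.26), where every sample correlated best with its own number.

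The test was tested on simulated data built from the ZBTB3 WT comparison at 48 h. Of 100 genes changed by a log2 of 1 edgeR called 96 and DESeq2 98, and of 100 changed by a log2 of 2 both called 100, with 9 and 14 false calls among 15764 genes. A GC trend added to the simulated counts gave 5756 false calls without correction and 11 with it. camera gave 8.02e-78 for a shifted list of 30 genes and 0.855 for an unchanged one. These numbers hold for that comparison only. The changed genes were drawn from genes of higher expression, so recovery was not measured for genes near 1 CPM. Counts were drawn with the spread edgeR had estimated per gene, alike in all libraries, so outlying replicates were not simulated. The simulated genes were drawn independently, so the camera result does not speak for lists whose genes move together. The added GC trend was smooth and alike in the 3 libraries of a group, a form that the correction fits by design. Depth was 7.6 to 23.6 M (mega) counts per library for ZBTB3 and 10.4 to 33.8 M for ZBTB9, so a gene at 1 CPM rested on about 7.6 to 33.8 counts per library. With 3 libraries against 3, an exact permutation p of a single gene cannot go under 0.1, so no permutation p is given for single genes. R 4.3.3, Python 3.11.15 and matplotlib 3.10.9 were used. No sample was left out.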

Results

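The data were RNA-seq gene counts from HEK293T cells, a human embryonic kidney line, with ZBTB3 or ZBTB9 knocked out, and from knockout cells that carried a transgene switched on by doxycycline. ZBTB3 (chromosome 11, 62750963 to 62754160) and ZBTB9 (chromosome 6, 33453083 to 33457544 in hg38) encode transcription factors with a BTB domain. The transgene was wild type (WT) or a point mutant, K116A for ZBTB3 and W128A for ZBTB9, which the series describes as unable to polymerize. Each gene had 17 groups of 3 libraries. They were parental cells at 0 h, knockout cells without transgene, and the WT and mutant lines. All but the parental cells had DMSO (the solvent control) for 24 h and for 48 h and doxycycline at 1 ug/mL for 48 h. For 24 h doxycycline was given at 0.1 ug/mL to the knockout cells and at 0.01, 0.1 or 1 ug/mL to the transgene lines. Libraries held 7.6 to 23.6 M (mega) counts (median 18.5 M) in the ZBTB3 table and 10.4 to 33.8 M (median 21.1 M) in the ZBTB9 table. The 3 parental libraries were the same in both tables, so the knockout comparisons of the 2 genes were not independent. Below, levels are CPM (counts scaled to a common library total) ± SD over 3 libraries, log2 fold changes carry ± their standard error, and a gene was called when its adjusted p from the edgeR quasi-likelihood test was under 0.05. Nothing in the labels said whether replicates were separate cultures, so each p-value measured spread between these samples alone.

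ZBTB3 stood at 4.02 ± 0.14 CPM in parental cells and at 2.75 ± 0.31 CPM in ZBTB3 knockout cells (log2 fold change -0.54 ± 0.20, adjusted p = 0.0365). Knockout cells given doxycycline at 0.1 ug/mL for 24 h held 5.11 ± 0.29 CPM, and the 48 h knockout groups held 2.48 ± 0.20 with DMSO and 3.26 ± 0.41 with doxycycline. In the WT line ZBTB3 stood at 2.64 ± 1.1 CPM with DMSO and at 2.75 ± 0.41, 2.59 ± 0.49 and 2.60 ± 0.52 at 0.01, 0.1 or 1 ug/mL for 24 h. At 48 h it was 2.92 ± 0.70 CPM with DMSO and 1.82 ± 0.64 with doxycycline. In the K116A line the 24 h levels were 3.10 ± 0.17, 3.01 ± 0.46, 2.47 ± 0.46 and 3.36 ± 0.17 CPM in the same order, and the 48 h levels 2.25 ± 0.48 and 3.46 ± 0.71. At 24 h ZBTB3 was not called at any dose in either line, and at 48 h it fell with WT and rose with K116A, calls that several other fits did not keep. The gene counts thus gave no clear sign of the ZBTB3 transgene, and how far its reads could be counted under ZBTB3 was not stated.

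ZBTB9 fell from 24.8 ± 0.57 CPM in parental cells to 14.7 ± 1.1 CPM in ZBTB9 knockout cells (log2 fold change -0.76 ± 0.12, adjusted p = 4.74e-06). Doxycycline left the knockout cells at 15.2 ± 1.6 CPM after 24 h, and the 48 h groups held 15.4 ± 0.31 with DMSO and 14.2 ± 0.68 with doxycycline. In the WT line it stood at 17.6 ± 1.1 CPM with DMSO and at 17.5 ± 1.6, 22.8 ± 3.2 and 30.1 ± 1.2 at 0.01, 0.1 or 1 ug/mL for 24 h, and it went from 18.8 ± 0.88 to 51.5 ± 7.7 CPM at 48 h (1.45 ± 0.12, adjusted p = 2.08e-10). In the W128A line the 24 h levels were 17.3 ± 1.6, 16.5 ± 1.6, 23.5 ± 4.4 and 26.9 ± 2.9 CPM, and it rose from 18 ± 1.2 to 40.4 ± 6.4 CPM at 48 h (1.16 ± 0.12, adjusted p = 1.72e-07). The WT and W128A inductions at 48 h differed by 0.29 ± 0.17 on the log2 scale (adjusted p = 0.229), so the transgenes were not shown to differ in level. In ZBTB3 knockout cells ZBTB9 stood at 24.7 ± 0.78 CPM, against 23.3 ± 0.59 in parental cells as scaled in that table.

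**Figure D1:**
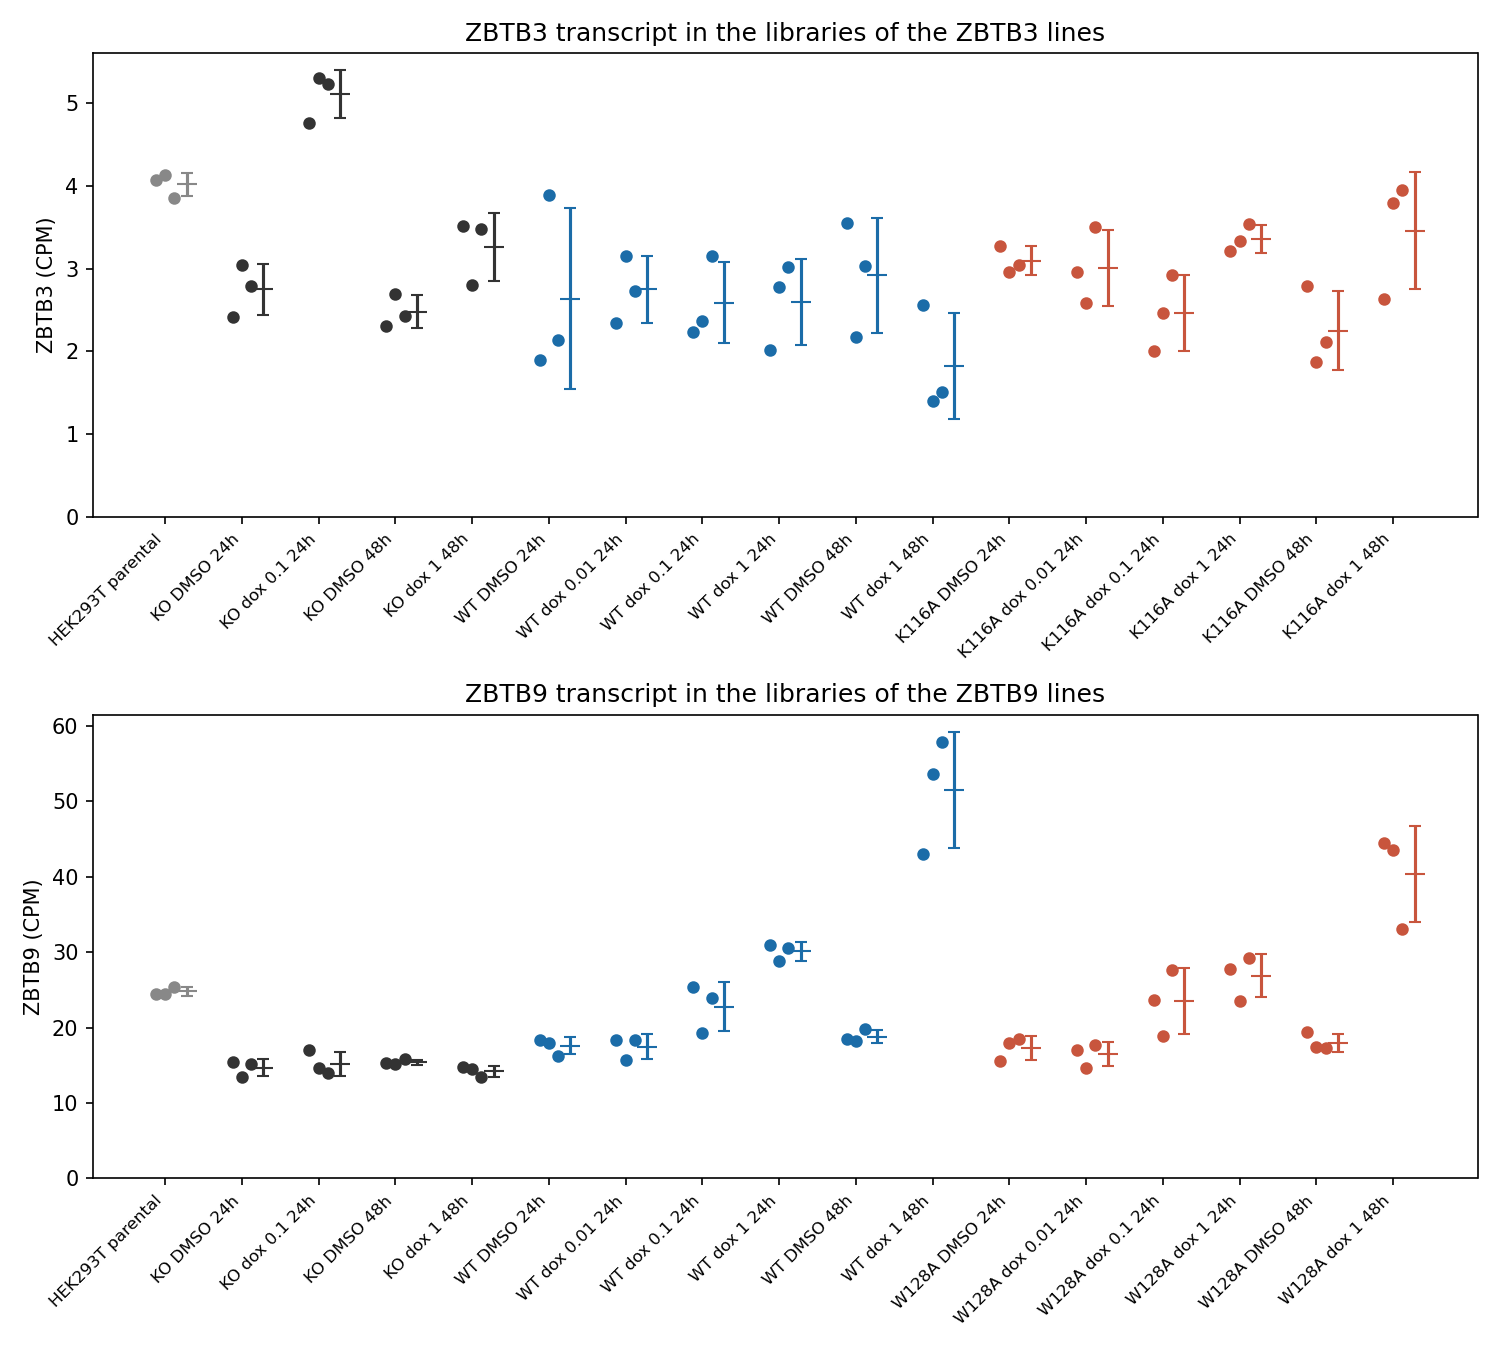
ZBTB3 and ZBTB9 in each library of their own table, in CPM. ZBTB9 rose with doxycycline at 48 h in both transgene lines, while the mean of ZBTB3 in both of its transgene lines stayed under the parental mean.

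Which genes differed after ZBTB3 was knocked out was read from knockout cells with DMSO for 24 h against parental cells. P4HTM, a transmembrane prolyl hydroxylase, rose from 0.396 ± 0.0786 to 5.70 ± 0.895 CPM (log2 fold change 3.82 ± 0.24, adjusted p = 1.28e-18), and the Wnt ligand WNT5B rose from 7.26 ± 0.364 to 30.3 ± 0.426 CPM (2.06 ± 0.081, 2.09e-26). PLP2, a membrane protein, fell from 17.8 ± 0.911 to 0.251 ± 0.172 CPM (-6.12 ± 0.51, 6.56e-13). BEX1 was listed at 0 in knockout cells against 33.9 ± 1.62 CPM, at least 636-fold lower, and the neuronal gene STMN2 at 0 against 2.73 ± 0.345 CPM, at least 51.3-fold lower. DESeq2 did not call BEX1 (adjusted p = 0.304), whose groups were 3 libraries without a count against 3 with many. Of 17 interferon response genes 1 rose, 8 fell and 8 were not called (1 and 9 when adjusted over the list alone), with IFI6 falling from 7.31 ± 0.83 to 2.89 ± 0.307 CPM and IFIT1 from 5.25 ± 0.294 to 1.71 ± 0.507 CPM. The list test gave adjusted p = 0.0287, and adjusted p = 0.109 with an estimated correlation. Of 76 ribosomal protein genes 29 rose, 2 fell and 45 were not called (35 and 3 when adjusted over the list alone), RPL14 by 0.35 ± 0.056 (adjusted p = 1.82e-06). The list test gave 1.13e-06 for them, and adjusted p = 0.808 with an estimated correlation. Among 53 genes of G2 and M phase 3 rose, 19 fell and 31 were not called (4 and 20 when adjusted over the list alone), with KIF23 falling from 120 ± 3.77 to 84.2 ± 1.72 CPM (adjusted p = 0.0218, and adjusted p = 0.712 with an estimated correlation). In all, 2320 genes were higher and 2748 lower of 16160 tested, 167 and 582 of them by at least 2-fold, and the groups did not overlap for 49% of genes, where chance gives 10%. With 1 knockout line in the labels, differences that arose while the line was made could not be separated from the effect of losing ZBTB3. The parental titles name no treatment and their labels give DMSO and 0 h, so treatment and time were not clearly matched between the groups.

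Doxycycline was compared with DMSO in ZBTB3 knockout cells without transgene, first at 0.1 ug/mL for 24 h. RN7SL1 and RN7SL2, near-identical copies of the signal recognition particle RNA whose reads are hard to tell apart, rose from 12.6 ± 1.02 to 252 ± 38.5 and from 12.5 ± 1.03 to 256 ± 39.4 CPM (log2 fold changes 4.32 ± 0.30 and 4.35 ± 0.29, adjusted p = 1.51e-12 and 1.16e-12). The nuclear RNA MALAT1 rose from 19.5 ± 3.63 to 100 ± 20.9 CPM (2.37 ± 0.29, 4.25e-07). RARB, a retinoic acid receptor, fell from 6.75 ± 0.611 to 3.47 ± 0.528 CPM (-0.96 ± 0.20, 0.00025). ZBTB3 itself rose by 0.89 ± 0.20 (adjusted p = 0.000811). The same control libraries served in the knockout contrast, so the rise of ZBTB3 here and its fall there were not independent. Of 23 p53 targets 13 rose, 1 fell and 9 were not called (the same numbers when adjusted over the list alone), among them CDKN1A from 32.7 ± 2.81 to 63.8 ± 3.82 CPM, TNFRSF10B from 81.0 ± 2.43 to 118 ± 9.66 and FDXR from 35.1 ± 2.77 to 51.8 ± 4.48 (list adjusted p = 1.14e-05, and adjusted p = 0.00398 with an estimated correlation). Of 53 genes of G2 and M phase 34 fell, 1 rose and 18 were not called (38 and 1 when adjusted over the list alone), with HMMR falling from 56.5 ± 2.98 to 42.1 ± 1.94 CPM and HMGB2 from 282 ± 0.682 to 214 ± 4.71 (6.19e-13, and adjusted p = 0.0175 with an estimated correlation). Of 13 mitochondrially encoded genes 7 rose and 6 were not called (9 when adjusted over the list alone), ND2 by 0.72 ± 0.16 (0.000261, and adjusted p = 0.595 with an estimated correlation). Higher genes numbered 2287 and lower genes 2215, and the groups did not overlap for 46.3% of genes (10% by chance). After GC and length correction 3372 were called, 2355 of them among the 4502. The slope on GC content (log2 per 10 points) averaged -0.024 in the control and 0.136 in the treated libraries. The control libraries are titled DMSO for 24 h, but the deposited sample sheet gives them 0 h and no treatment, so this contrast was not clearly one of doxycycline alone. The labels gave no word on whether these treated and control libraries were made side by side.

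At 1 ug/mL for 48 h doxycycline changed far fewer genes in the ZBTB3 knockout cells. CHRNA5, a nicotinic receptor subunit, fell from 35.1 ± 3.66 to 27.1 ± 0.676 CPM (log2 fold change -0.37 ± 0.069, adjusted p = 0.0115), and the receptor GPR37 rose from 1.42 ± 0.431 to 3.19 ± 0.191 CPM (1.16 ± 0.24, 0.042). Both calls rested on single libraries. Without doxycycline replicate 2, doxycycline replicate 3 or DMSO replicate 1 the adjusted p became 0.16, 0.114 and 0.168 for CHRNA5 and 0.16, 0.171 and 0.0583 for GPR37, which also lost its call without DMSO replicate 2 (0.165). ZBTB3 was not called (0.39, adjusted p = 0.515). Of 53 genes of G2 and M phase 1 fell and 52 were not called (8 when adjusted over the list alone), and the list moved down by a median of -0.07 (adjusted p = 3.72e-07, and adjusted p = 0.349 with an estimated correlation). The whole test called 6 genes higher and 6 lower, and 13 and 7 after GC and length correction. Without DMSO replicates 1, 2 and 3 the count was 3, 4 and 17, and without doxycycline replicates 1, 2 and 3 it was 120, 1 and 1. Groups did not overlap for 17.3% of genes, where chance gives 10%. Whether the 2 doxycycline settings differed from each other was not tested.

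The response of the WT ZBTB3 line was read at 3 doses of doxycycline after 24 h, against the same 3 DMSO libraries. No comparison subtracted the effect of doxycycline itself, here or in the other lines. At 0.1 ug/mL the kinase gene DYRK1A fell from 67.6 ± 1.70 to 51.4 ± 5.61 CPM (log2 fold change -0.39 ± 0.068, adjusted p = 0.00277) and MIDN from 254 ± 10 to 185 ± 16.2 CPM (-0.46 ± 0.082, 0.00512). MIDN was no longer called without replicate 2 of that dose (0.215). At 1 ug/mL the proteoglycan gene SDC2 rose from 67.3 ± 1.25 to 83.0 ± 5.22 CPM (0.30 ± 0.050, 0.00173) and ZNRF2 fell from 21.4 ± 0.537 to 14.7 ± 1.42 CPM (-0.54 ± 0.090, 0.00173), both lost without replicate 1 of that dose (0.183 for each). At 0.01 ug/mL edgeR called 0 genes, with 1835 under an unadjusted p of 0.05 and 44 called by DESeq2. At the middle dose 31 genes were higher and 73 lower, and at 1 ug/mL 21 and 37. These counts moved with single libraries. At 0.01 ug/mL leaving out replicate 3 of the dose gave 350 calls, and each other omission gave 0. At the middle dose the count was 13, 12 and 28 without DMSO replicates 1, 2 and 3 and 83, 2 and 536 without doxycycline replicates 1, 2 and 3, and at 1 ug/mL it was 6, 3 and 19 and then 0, 5 and 424. Replicate 3 of these doses lay apart, with a chi-square per gene of 2.33, 5.59 and 3.95 between replicates 1 and 2 and of 9.4 to 14.9 between either and replicate 3. With a replicate block fitted within the 24 h doxycycline groups, chosen after the counts were seen, the 3 doses gave 480, 930 and 769 calls.

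Some lists passed their test at the 3 doses of the WT ZBTB3 line. The list tests were not repeated without replicate 3. Of 31 ATF4 and amino acid stress genes none was called among all genes, and 17, 18 and 16 rose when adjusted over the list alone at 0.01, 0.1 or 1 ug/mL, with list medians of 0.20, 0.22 and 0.21. Their list test gave adjusted p = 4.61e-13, 2.53e-09 and 1.53e-12. With the correlation estimated from the data none of the doses held, with adjusted p = 0.247, adjusted p = 0.267 and adjusted p = 0.136 with an estimated correlation. Of 76 ribosomal protein genes 0, 6 and 1 rose and 76, 70 and 75 were not called (2, 48 and 40 when adjusted over the list alone). The list test gave 2.11e-12, 7.73e-31 and 4.83e-26, and adjusted p = 0.4, 0.225 and 0.153 with an estimated correlation. Many of these genes stood lower in the WT than in the K116A line with DMSO for 24 h, so the rise was read against a low control. At 1 ug/mL 2 of 13 mitochondrially encoded genes fell and 11 were not called (11 fell when adjusted over the list alone). One of them, ND5, fell from 1940 ± 90.9 to 902 ± 359 CPM (-1.10 ± 0.25, adjusted p = 0.0333). The median of this list was -0.81 (3.5e-18, and adjusted p = 0.0776 with an estimated correlation). The fall was read against a high control. Mitochondrial mRNA made up 3.02% (SD 0.07) of counts in the WT DMSO libraries and 1.85% (SD 0.57) at 1 ug/mL. With DMSO for 24 h it made up 1.89% in knockout and 1.99% in K116A cells. Sharing 1 set of DMSO libraries makes the doses resemble each other even where doxycycline had no effect.

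At 48 h with 1 ug/mL more genes were called in the WT ZBTB3 line. ENAH, a regulator of actin filaments, rose from 393 ± 4.29 to 854 ± 17.8 CPM (log2 fold change 1.12 ± 0.048, adjusted p = 3.41e-24), and PLPPR4 rose from 1.04 ± 0.552 to 3.67 ± 0.698 CPM (1.80 ± 0.33, 1.49e-05). PRR22 fell from 3.50 ± 0.612 to 1.19 ± 0.242 CPM (-1.53 ± 0.27, 9.34e-06). Of 31 ATF4 and amino acid stress genes 3 rose, 12 fell and 16 were not called (3 and 13 when adjusted over the list alone), with SESN2 falling from 207 ± 8.03 to 117 ± 8.88 CPM and ATF5 from 15.8 ± 1.13 to 8.49 ± 1.82. Of 17 heat shock genes 5 rose, 2 fell and 10 were not called (5 and 2 when adjusted over the list alone), among them HSPE1 from 141 ± 0.793 to 211 ± 7.39 CPM and HSPD1 from 1310 ± 31.7 to 1620 ± 20.8 CPM. No list passed its test here. The ZBTB3 gene fell by 0.65 on the log2 scale (standard error 0.24, adjusted p = 0.026), a call lost after correction for GC content and length (0.271) and without DMSO replicate 1 (0.135) or 3 (0.0674) or doxycycline replicate 2 (0.149) or 3 (0.128). Genes called higher numbered 3102 and lower 3573, with groups apart for 53% of genes (10% by chance). After the same correction the count was 2094, of which 1408 were among the 6675.

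The K116A mutant was read in the same way, with the 3 doses at 24 h again sharing their DMSO libraries. At 0.1 ug/mL TBX2, a T-box transcription factor, fell from 36.3 ± 2.40 to 23.9 ± 3.89 CPM (log2 fold change -0.60 ± 0.12, adjusted p = 0.00598), and STARD4, a sterol carrier, rose from 15 ± 0.166 to 22.4 ± 1.81 CPM (0.58 ± 0.11, 0.00194). Neither was called when the fit held only the groups compared (0.0713 and 0.0668) or without replicate 2 of the dose (0.157 and 0.0748). At 1 ug/mL SALL3 fell from 33.1 ± 2.29 to 23.4 ± 0.515 CPM (-0.50 ± 0.11, 0.018), which was lost without DMSO replicate 1 (0.0757) or 3 (0.112) and without doxycycline replicate 1 (0.208) or 2 (0.0782). Among 31 ATF4 and amino acid stress genes 2 rose, 1 fell and 28 were not called at 0.1 ug/mL (6 and 1 when adjusted over the list alone), and none was called at 1 ug/mL (9 higher when adjusted over the list alone). Their tests gave adjusted p = 0.00173 and 2.44e-06, and adjusted p = 0.718 and 0.433 with an estimated correlation. At 0.01 ug/mL edgeR called 0 genes, with 1996 under an unadjusted p of 0.05 and 1 called by DESeq2. At the middle dose 180 genes were higher and 455 lower, and at 1 ug/mL 37 and 105. A fit of only the groups compared called 0 and 6 genes at these 2 doses, and GC and length correction 148 and 206. At 0.01 ug/mL leaving out replicate 3 of the dose gave 500 calls and each other omission 0. At 0.1 ug/mL the count was 163, 550 and 42 without DMSO replicates 1, 2 and 3 and 820, 3 and 994 without doxycycline replicates 1, 2 and 3, and at 1 ug/mL 11, 94 and 1 and then 1, 6 and 1166. Replicate 3 lay apart here too, with a chi-square per gene of 11.2 to 23.8 against replicates 1 and 2, and of 4.22, 10.2 and 4.59 between those. The block within the 24 h doxycycline groups gave 663, 1622 and 1128 calls.

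After 48 h the K116A line held many changed genes. The fucosyltransferase gene FUT1 rose from 1.06 ± 0.00181 to 5.22 ± 1.12 CPM (log2 fold change 2.30 ± 0.47, adjusted p = 0.000202), and the transferrin receptor TFRC fell from 224 ± 9.73 to 122 ± 9.18 CPM (-0.88 ± 0.098, 6.6e-08). Of 31 ATF4 and amino acid stress genes 19 rose and 12 were not called (21 when adjusted over the list alone), with TRIB3 rising from 33.6 ± 5.15 to 56.1 ± 9.25 CPM, SESN2 from 95.3 ± 9.95 to 164 ± 16.1 and CHAC1 from 11.3 ± 1.83 to 29.9 ± 0.917 (list adjusted p = 5.74e-10, and adjusted p = 0.192 with an estimated correlation). Of 13 mitochondrially encoded genes 12 rose and 1 was not called (13 when adjusted over the list alone), among them ATP6, which overlaps ATP8, from 1980 ± 362 to 4350 ± 320 CPM and COX2 from 1790 ± 327 to 3490 ± 321 (1.75e-09, and adjusted p = 0.192 with an estimated correlation). Of 17 heat shock genes 11 fell and 6 were not called (12 when adjusted over the list alone), HSPE1 from 207 ± 12.8 to 119 ± 16.1 CPM and DNAJA1 from 200 ± 7.17 to 126 ± 11.8 (5.86e-06, and adjusted p = 0.206 with an estimated correlation). Of 53 genes of G2 and M phase 28 fell and 25 were not called (29 when adjusted over the list alone), CCNB1 from 203 ± 3.15 to 148 ± 2.30 CPM (4.17e-10, and adjusted p = 0.103 with an estimated correlation). ZBTB3 rose by 0.64 ± 0.24 (adjusted p = 0.0396), a call lost with no expression filter (0.0614), with only the groups compared (0.0668), after GC and length correction (0.129) and without DMSO replicate 2 (0.2) or 3 (0.089) or doxycycline replicate 2 (0.12) or 3 (0.16). In total 2178 genes were higher and 2680 lower, and groups did not overlap for 37.8% of genes (10% by chance). After GC and length correction 2455 were called, 1621 of them among the 4858, and without doxycycline replicate 3 the count was 3237. This was the one contrast whose replicate numbers paired, and the replicate block called 5066. That block held terms shared by all groups of the fit, so the pairs of these libraries were not modelled on their own.

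Whether the K116A mutation changed the response was tested as the difference between the WT and K116A inductions, which used 12 libraries at each dose. At 24 h edgeR called 0 genes at each dose, with 600, 453 and 559 under an unadjusted p of 0.05, and DESeq2 called 0, 0 and 1. At 48 h SESN2 differed by -1.61 ± 0.20 (adjusted p = 5.55e-08), TRIB3 by -1.32 ± 0.13 (1.16e-11) and the amino acid transporter SLC7A5 by -1.09 ± 0.10 (4.2e-11), each lower with WT and higher with K116A. These became -1.02, -0.68 and -0.41 after GC and length correction and stayed called. HSPE1 differed by 1.39 ± 0.15 (1.18e-09) and by 1.3 after that correction. Of the 31 ATF4 and amino acid stress genes 19 were lower, 1 higher and 11 not called (20 and 1 when adjusted over the list alone), and of 17 heat shock genes 10 were higher, 2 lower and 5 not called (the same when adjusted over the list alone). Their list tests gave adjusted p = 5.71e-05 and 0.00495, and adjusted p = 0.506 with an estimated correlation for each. The difference in ZBTB3 itself was -1.29 ± 0.34 (adjusted p = 0.00147). Counts came to 3883 higher and 4016 lower, falling to 2630 after GC and length correction, of which 1942 were shared. Every fit that left out 1 library called 7096 to 8105.

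**Figure D2:**
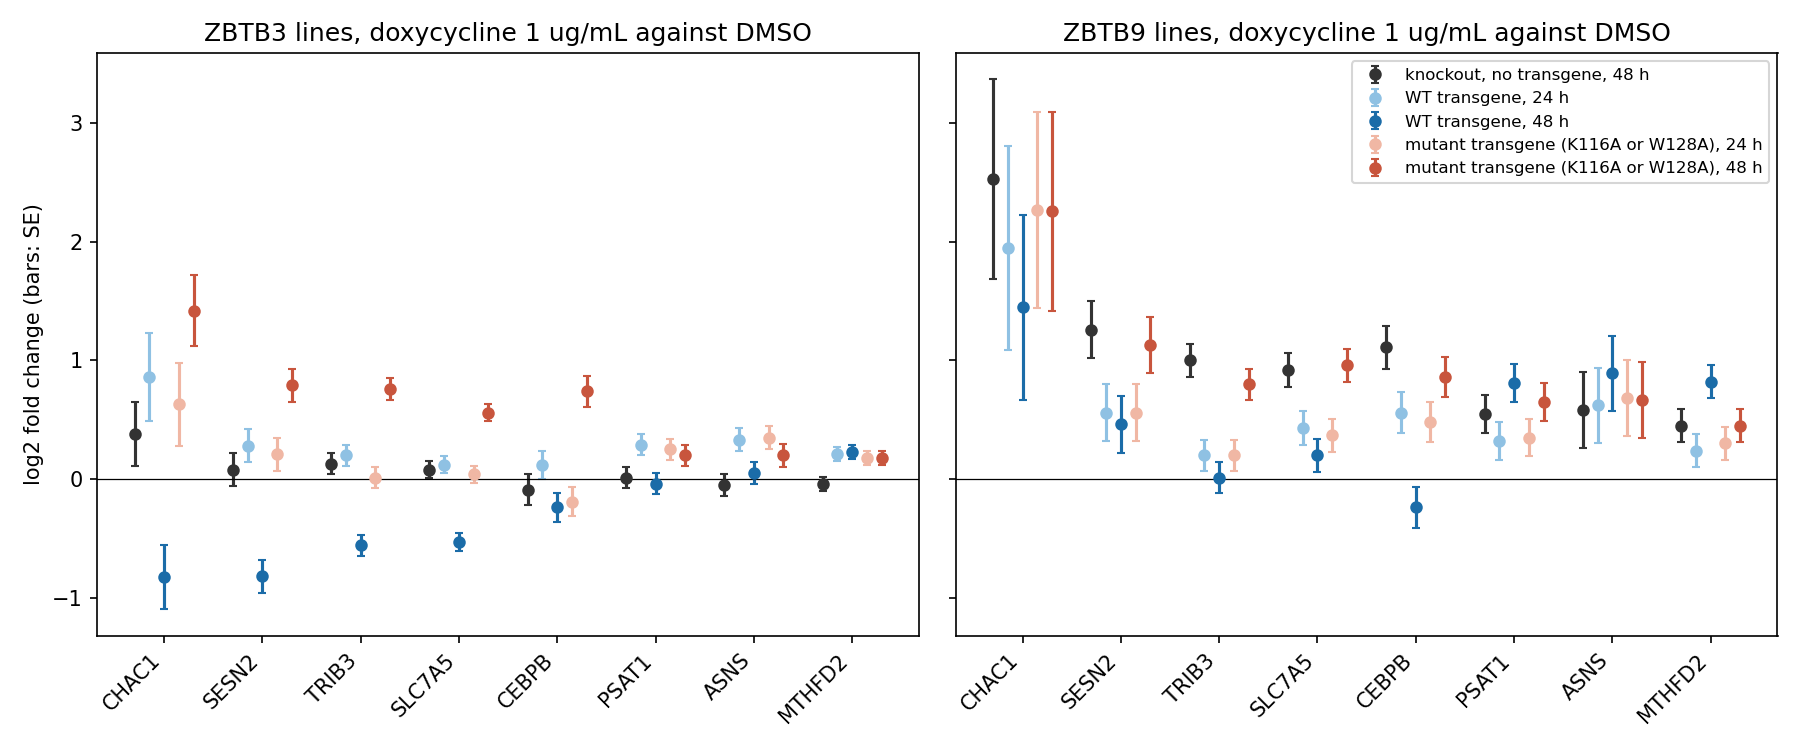
ATF4 and amino acid stress genes in the inductions at 1 ug/mL. Bars are standard errors, and CHAC1, SESN2, TRIB3 and SLC7A5 lay below 0 at 48 h in the WT ZBTB3 line and above 0 in the K116A line.

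Agreement between the WT and K116A responses was measured with no library shared. The correlation of log2 fold changes over all genes was 0.09, 0.17 and 0.30 at 0.01, 0.1 or 1 ug/mL for 24 h and -0.22 at 48 h, and over genes above the median expression 0.61, 0.73, 0.86 and -0.51. With 1 library left out r over all genes ran from 0.04 to 0.15, 0.10 to 0.19, 0.22 to 0.30 and -0.24 to -0.16. Genes are not independent replicates, so no p-value was attached. At 24 h the doxycycline groups of the 2 lines paired by replicate number (r of 0.56, 0.40 and 0.57 at 0.1 ug/mL), so a structure common to both adds to these correlations and to the shared genes, which chance counts do not allow for. At the middle dose 52 genes were lower in both lines where 2.06 would be shared by chance, and at 1 ug/mL 18 where chance gives 0.24, with 0 genes in opposite directions at either dose. In a fit of only the groups compared K116A had 0 calls at the middle dose and 6 at 1 ug/mL. At 48 h 2785 genes were called in opposite directions, 18 higher in both where chance gives 418, and 119 lower in both where chance gives 593. After GC and length correction the 48 h correlations were -0.06 and -0.09, and 447 genes were opposite, 52 higher in both where chance gives 56.4 and 87 lower in both where chance gives 106. TBX2 fell in both lines at 0.1 ug/mL (-0.58 ± 0.12 with WT and -0.60 ± 0.12 with K116A), though the WT call was lost without any 1 of the 3 DMSO libraries (0.0978, 0.0597 and 0.0608) or doxycycline replicate 2 (0.295). SESN2 and HSPE1 were among the genes of opposite direction at 48 h.

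The lines also differed before induction. With DMSO for 24 h SNAI2, a zinc finger repressor, was higher in K116A than in WT ZBTB3 cells (10.1 ± 0.777 against 4.84 ± 0.863 CPM, log2 fold change 1.06 ± 0.12, adjusted p = 1.46e-07), as was the sulfatase gene SULF1 (4.10 ± 0.282 against 1.73 ± 0.361 CPM, 1.25 ± 0.24, 0.00203). Of 76 ribosomal protein genes 38 were higher and 38 not called (70 when adjusted over the list alone), with RPL19 at 987 ± 24.7 against 781 ± 4.58 CPM and RPS14 at 753 ± 32.4 against 591 ± 5.05. Of 50 nuclear OXPHOS genes 15 were higher and 35 not called (34 when adjusted over the list alone), NDUFB9 at 123 ± 9.70 against 96.1 ± 1.65 CPM. The 2 lists gave adjusted p = 3.89e-51 and 2.55e-24, and adjusted p = 0.105 with an estimated correlation for each. The test called 324 genes higher and 124 lower, with groups apart for 26.5% of genes (10% by chance). Leaving out WT DMSO replicates 1, 2 and 3 gave 265, 122 and 200 calls, and leaving out K116A DMSO replicates 1, 2 and 3 gave 336, 1.2e+02 (rounded) and 287. For ZBTB9 the W128A and WT lines differed at 0 genes by edgeR, with 184 under an unadjusted p of 0.05 and 0 by DESeq2.

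**Figure D3:**
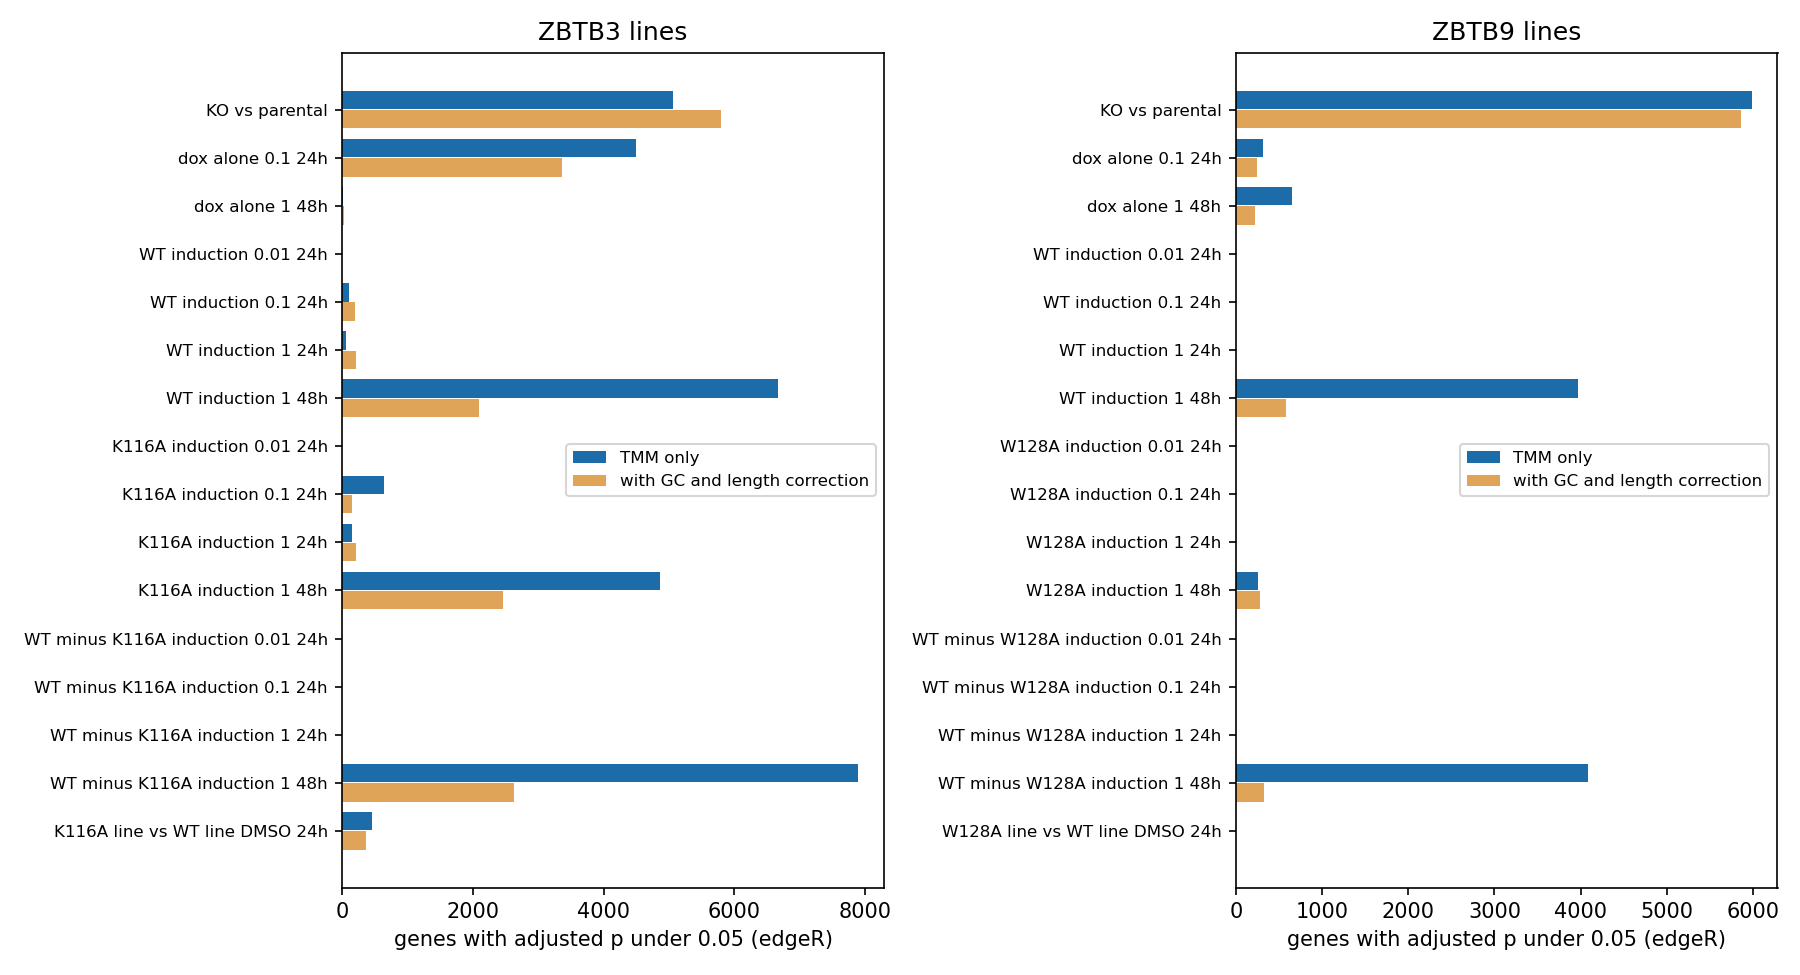
Number of genes called in each comparison under the planned test and with GC and length correction. Under the planned test each of the 4 transgene lines had more calls at 48 h than at any dose at 24 h. Of the knockout cells without transgene, under that test, those of ZBTB3 had fewer at 48 h and those of ZBTB9 more (649 against 309). The order for ZBTB9 turned after GC and length correction (226 against 247) and in a fit of only the groups compared (2674 against 5394).

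Knockout of ZBTB9 was compared with the same parental libraries, with the same limit on treatment and time. NLRP1, an inflammasome sensor, rose from 0.053 ± 0.055 to 8.68 ± 1.21 CPM (log2 fold change 7.20 ± 0.61, adjusted p = 3.06e-12), and IGSF1 from 0.373 ± 0.107 to 10.4 ± 1.17 CPM (4.79 ± 0.28, 1.81e-16). The actin crosslinker FLNC fell from 80.5 ± 4.59 to 0.832 ± 0.193 CPM (-6.60 ± 0.42, 1.53e-15), and BEX1 was listed at 0 against 36.0 ± 1.77 CPM, at least 923-fold lower. Of 40 S phase genes 30 fell and 10 were not called (31 when adjusted over the list alone), with EXO1 falling from 147 ± 2.50 to 55.0 ± 1.89 CPM and BLM from 84.6 ± 2.20 to 47.6 ± 1.80 (list adjusted p = 7.36e-14, and adjusted p = 0.209 with an estimated correlation). Of 23 p53 targets 10 fell, 1 rose and 12 were not called (the same when adjusted over the list alone), with CDKN1A falling from 28.1 ± 0.817 to 10.2 ± 0.584 CPM and BTG2 from 27.4 ± 1.71 to 14.4 ± 0.191 (0.000531, and adjusted p = 0.146 with an estimated correlation). Of 34 neuronal genes 19 rose, 2 fell and 13 were not called (the same when adjusted over the list alone), INA from 43.1 ± 1.28 to 126 ± 1.43 CPM and SYN1 from 1.78 ± 0.0272 to 5.13 ± 0.319, while STMN2 fell from 2.91 ± 0.368 to 0.131 ± 0.012 (0.000256, and adjusted p = 0.146 with an estimated correlation). Of 29 genes of glycolysis and hypoxia 12 rose and 17 were not called (12 when adjusted over the list alone), ENO2 from 10.4 ± 0.572 to 31.6 ± 0.605 CPM (0.00337, and adjusted p = 0.477 with an estimated correlation). Higher genes numbered 3078 and lower genes 2909 of 16961 tested, 1168 and 288 of them by at least 2-fold, with groups apart for 64.3% of genes (10% by chance). After GC and length correction 5868 were called, 4025 of them among the 5987, and 892 and 236 were higher and lower by at least 2-fold. The slope on GC content (log2 per 10 points) averaged -0.179 in parental and 0.118 in knockout libraries. The limit of having 1 knockout line holds here as well.

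In ZBTB9 knockout cells without transgene RN7SL1 and RN7SL2 were higher with doxycycline too, from 14.4 ± 1.38 to 264 ± 13.1 and from 14.9 ± 3.59 to 282 ± 20 CPM at 0.1 ug/mL for 24 h (log2 fold changes 4.20 ± 0.31 and 4.23 ± 0.35, adjusted p = 5.61e-12 and 1.59e-10). Of 23 p53 targets 7 rose and 16 were not called (14 when adjusted over the list alone), among them CDKN1A from 10.2 ± 0.584 to 32.8 ± 6.19 CPM, RPS27L from 14.6 ± 0.616 to 28.3 ± 0.736 and SESN1 from 20.8 ± 1.42 to 33.4 ± 1.73 (list adjusted p = 1.67e-14, and adjusted p = 8.69e-05 with an estimated correlation). The same DMSO libraries served in the knockout contrast, so this rise of p53 targets and their fall there were not independent. With doxycycline CDKN1A stood near its parental level. NKX2-4, a homeobox gene, fell from 17.1 ± 1.05 to 8.86 ± 0.967 CPM (-0.95 ± 0.18, adjusted p = 0.0021). The test called 129 genes higher and 180 lower, and after GC and length correction 145 and 102, of which 139 were among the 309. A fit of only these groups called 5394 genes, so the count depended strongly on which groups shared the estimate of spread. Without DMSO replicates 1, 2 and 3 the count was 60, 115 and 138, and without doxycycline replicates 1, 2 and 3 it was 88, 80 and 126. Groups did not overlap for 42.9% of genes (10% by chance).

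The longer treatment of ZBTB9 knockout cells, 1 ug/mL for 48 h, moved stress genes. G0S2, an inhibitor of lipid breakdown, rose from 5.19 ± 1.5 to 13.2 ± 2.10 CPM (log2 fold change 1.34 ± 0.22, adjusted p = 0.000718). Of 31 ATF4 and amino acid stress genes 14 rose and 17 were not called (20 when adjusted over the list alone), with TRIB3 rising from 29.6 ± 1.17 to 59.1 ± 15.1 CPM, SLC7A5 from 285 ± 14.1 to 542 ± 107 and SHMT2 from 306 ± 12.3 to 462 ± 51 (list adjusted p = 4.12e-20, and adjusted p = 0.145 with an estimated correlation). PLOD2, a lysyl hydroxylase, fell from 169 ± 14.6 to 106 ± 12.4 CPM (-0.68 ± 0.12, adjusted p = 0.000983), a call lost without doxycycline replicate 3 (0.0546). Called genes came to 463 higher and 186 lower, with groups apart for 33.7% of genes (10% by chance). A fit of only these groups called 2674, and GC and length correction gave 226. Without DMSO replicates 1, 2 and 3 the count was 137, 95 and 357, and without doxycycline replicates 1, 2 and 3 it was 1855, 126 and 13.

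At 24 h nearly all genes stayed uncalled in the ZBTB9 transgene lines. In the WT line at 1 ug/mL ZBTB9 itself rose (0.78 ± 0.12, adjusted p = 0.00239) and was the 1 gene called by edgeR, with 1067 under an unadjusted p of 0.05 and 3 by DESeq2. A fit of only the groups compared did not call it (0.46). At 0.01 and 0.1 ug/mL edgeR called 0 genes, with 618 and 1191 under an unadjusted p of 0.05 and 2 by DESeq2 at each dose. In the W128A line edgeR called 0 genes at 0.01, 0.1 or 1 ug/mL, with 572, 488 and 1225 under an unadjusted p of 0.05 and 3, 2 and 10 by DESeq2. ZBTB9 in that line was not called at 1 ug/mL (0.63 ± 0.12, adjusted p = 0.0941). At 0.01 ug/mL of W128A leaving out doxycycline replicate 1 or 3 gave 1 and 2 calls, and at 1 ug/mL leaving out doxycycline replicate 2 gave 1. Replicate 2 of each 24 h doxycycline group lay apart from replicates 1 and 3, and with a replicate block fitted within the 24 h doxycycline groups the WT counts became 119, 766 and 538 and the W128A counts 883, 693 and 1850. Among 31 ATF4 and amino acid stress genes 7 rose at 1 ug/mL in each line when adjusted over the list alone and none among all genes (list adjusted p = 6.98e-11 with WT and 5.69e-10 with W128A, and adjusted p = 0.457 and 0.505 with an estimated correlation). In replicate 2 of the 6 groups 27 of these 31 genes stood above replicates 1 and 3 (median 0.47), so those libraries carry part of the rise. The doses shared 3 DMSO libraries per line. Across all genes WT and W128A changes correlated at 0.29, 0.33 and 0.35 over the 3 doses, and above the median expression at 0.62, 0.63 and 0.80, with the doxycycline groups again paired by number. Leaving out 1 library moved r across all genes between -0.10 and 0.33, between -0.07 and 0.38 and between -0.09 and 0.41.

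At 48 h doxycycline changed many genes in the WT ZBTB9 line. RELB, an NF-kappa-B subunit, fell from 5.18 ± 1.61 to 1.61 ± 0.429 CPM (log2 fold change -1.67 ± 0.22, adjusted p = 1.25e-05), and BEND6 rose from 0.712 ± 0.248 to 2.12 ± 0.272 CPM (1.53 ± 0.29, 0.000453). Among 31 ATF4 and amino acid stress genes 11 rose and 20 were not called (13 when adjusted over the list alone), MTHFD2 from 309 ± 50.3 to 547 ± 31.1 CPM and PSPH from 42.2 ± 7 to 68.0 ± 3.45 (list adjusted p = 4.19e-06, and adjusted p = 0.471 with an estimated correlation). Of 29 genes of glycolysis and hypoxia 9 fell and 20 were not called (11 when adjusted over the list alone), SLC2A1 from 82.3 ± 16.5 to 46.3 ± 2.84 CPM and NDRG1 from 101 ± 10.4 to 71.6 ± 2 (4.75e-06, and adjusted p = 0.412 with an estimated correlation). Of 28 immediate early genes 14 fell, 1 rose and 13 were not called (16 and 1 when adjusted over the list alone), FOSB from 4.09 ± 0.442 to 1.29 ± 0.415 CPM (3.32e-06, and adjusted p = 0.0555 with an estimated correlation). Calls came to 1902 higher and 2071 lower, with groups apart for 34.1% of genes (10% by chance). The DMSO libraries stood apart from each other, with a chi-square per gene of 10.9, 38.5 and 68.8 between pairs (3.51 to 4.12 with doxycycline) and slopes on GC content (log2 per 10 points) from -0.119 to 0.354, and the list tests used all of them. A fit of only these 6 libraries called 1 gene, ZBTB9, and gave 0.114 for each other gene named here. Without DMSO replicates 1, 2 and 3 the count was 2399, 837 and 6335, and without doxycycline replicates 1, 2 and 3 it was 3185, 3089 and 2701. GC and length correction gave 585, of which 351 were shared.

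In the W128A line at 48 h G0S2 rose from 3.95 ± 1.16 to 11.7 ± 1.10 CPM (log2 fold change 1.56 ± 0.23, adjusted p = 8.53e-05), and of 31 ATF4 and amino acid stress genes 13 rose and 18 were not called (20 when adjusted over the list alone). Among them TRIB3 rose from 30 ± 0.998 to 52.3 ± 8.66 CPM, SLC7A5 from 249 ± 12 to 484 ± 57.3 and SHMT2 from 301 ± 5.58 to 433 ± 31 (list adjusted p = 3.7e-22, and adjusted p = 0.133 with an estimated correlation). P4HA1, a collagen prolyl hydroxylase, fell from 111 ± 5.18 to 73.8 ± 7.26 CPM (-0.59 ± 0.11, adjusted p = 0.00395), a call lost without doxycycline replicate 3 (0.111). The test called 170 genes higher and 80 lower, and 150 and 126 after GC and length correction, with groups apart for 35.1% of genes (10% by chance). A fit of only these groups called 2977, against 1 in the WT line, so which line had more calls turned with the fit. Without DMSO replicates 1, 2 and 3 the count was 34, 56 and 134, and without doxycycline replicates 1, 2 and 3 it was 626, 93 and 13. Many of the 250 genes were also called with doxycycline in knockout cells that held no transgene, 121 of them higher in both where chance gives 4.64, 34 lower in both where chance gives 0.877 and 0 opposite. The correlation was 0.32 over all genes and 0.86 above the median expression. G0S2, TRIB3, SLC7A5 and SHMT2 were called in both.

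Whether W128A changed the response to ZBTB9 was tested as the difference between inductions. At 24 h edgeR called 0 genes at each dose, with 188, 215 and 167 under an unadjusted p of 0.05 and 0, 0 and 2 by DESeq2. At 48 h CAMK2N2, an inhibitor of CaM kinase, differed by -2.74 ± 0.40 (adjusted p = 0.000115), falling from 8.06 ± 3.47 to 2.22 ± 0.427 CPM with WT and standing at 2.41 ± 0.444 with DMSO and 4.42 ± 1.40 with doxycycline in the W128A line. TRIB3 and SLC7A5 differed by -0.79 ± 0.19 and -0.76 ± 0.19 (0.00301 and 0.00484), but after GC and length correction by -0.22 and -0.14 (0.584 and 0.829). Of 50 nuclear OXPHOS genes 10 were higher, 3 lower and 37 not called (the same when adjusted over the list alone), NDUFA1 by 0.71 ± 0.16 and NDUFS8 by -1.07 ± 0.22 (list adjusted p = 0.0294, and adjusted p = 0.905 with an estimated correlation). Called genes numbered 1992 higher and 2100 lower, and 322 after GC and length correction, of which 199 were shared. Leaving out WT DMSO replicate 2 gave 2024 and W128A doxycycline replicate 3 gave 2254. The WT and W128A changes at 48 h correlated at -0.09 over all genes (-0.13 to 0.01 with 1 library left out) and at -0.39 above the median expression, and after GC and length correction at 0.06 and 0.26.

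Whether induction moved the genes altered by knockout back was asked with genes that differed by at least 2-fold, in knockout lists that share no library with the inductions. For ZBTB3, 66.3% of the 582 genes lower in knockout cells stood higher with WT at 1 ug/mL for 24 h (51.3% of all genes, adjusted p = 0.000816, and adjusted p = 0.262 with an estimated correlation), and 67.4% with K116A (51.7%, 0.00192, and adjusted p = 0.262 with an estimated correlation). At 48 h the share was 43% with WT (49.2% of all genes, adjusted p = 0.825) and 68.7% with K116A (51.1%, 0.00192, and adjusted p = 0.262 with an estimated correlation). The WT share at 48 h would turn into its complement if the DMSO and doxycycline labels of those libraries were exchanged, which ZBTB3 counts could not rule out, and it was 57.5% (0.353) after GC and length correction. The 167 genes higher in ZBTB3 knockout cells gave no call. For ZBTB9, the 1168 genes higher in knockout cells stood lower in 22.7% with WT and 23.4% with W128A at 24 h (45% and 49.8% of all genes), so most had a log2 fold change above 0, with none of them called (5.25e-06 and 6.06e-08, and adjusted p = 0.443 with an estimated correlation for each). At 48 h the share was 62.9% with WT (46.8%, 0.00181, and adjusted p = 0.596 with an estimated correlation), 44.4% after GC and length correction, and 23% with W128A (48%, 2.97e-07, and adjusted p = 0.443 with an estimated correlation). Of the 288 genes lower in ZBTB9 knockout cells 63.5% stood higher with WT at 48 h (53.1%, 0.0179, and adjusted p = 0.439 with an estimated correlation), and 54.2% after GC and length correction. None of these lists of genes such as NLRP1, FLNC, P4HTM and PLP2 therefore moved back in the WT lines in a way that held under both forms of the test.

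**Figure D4:**
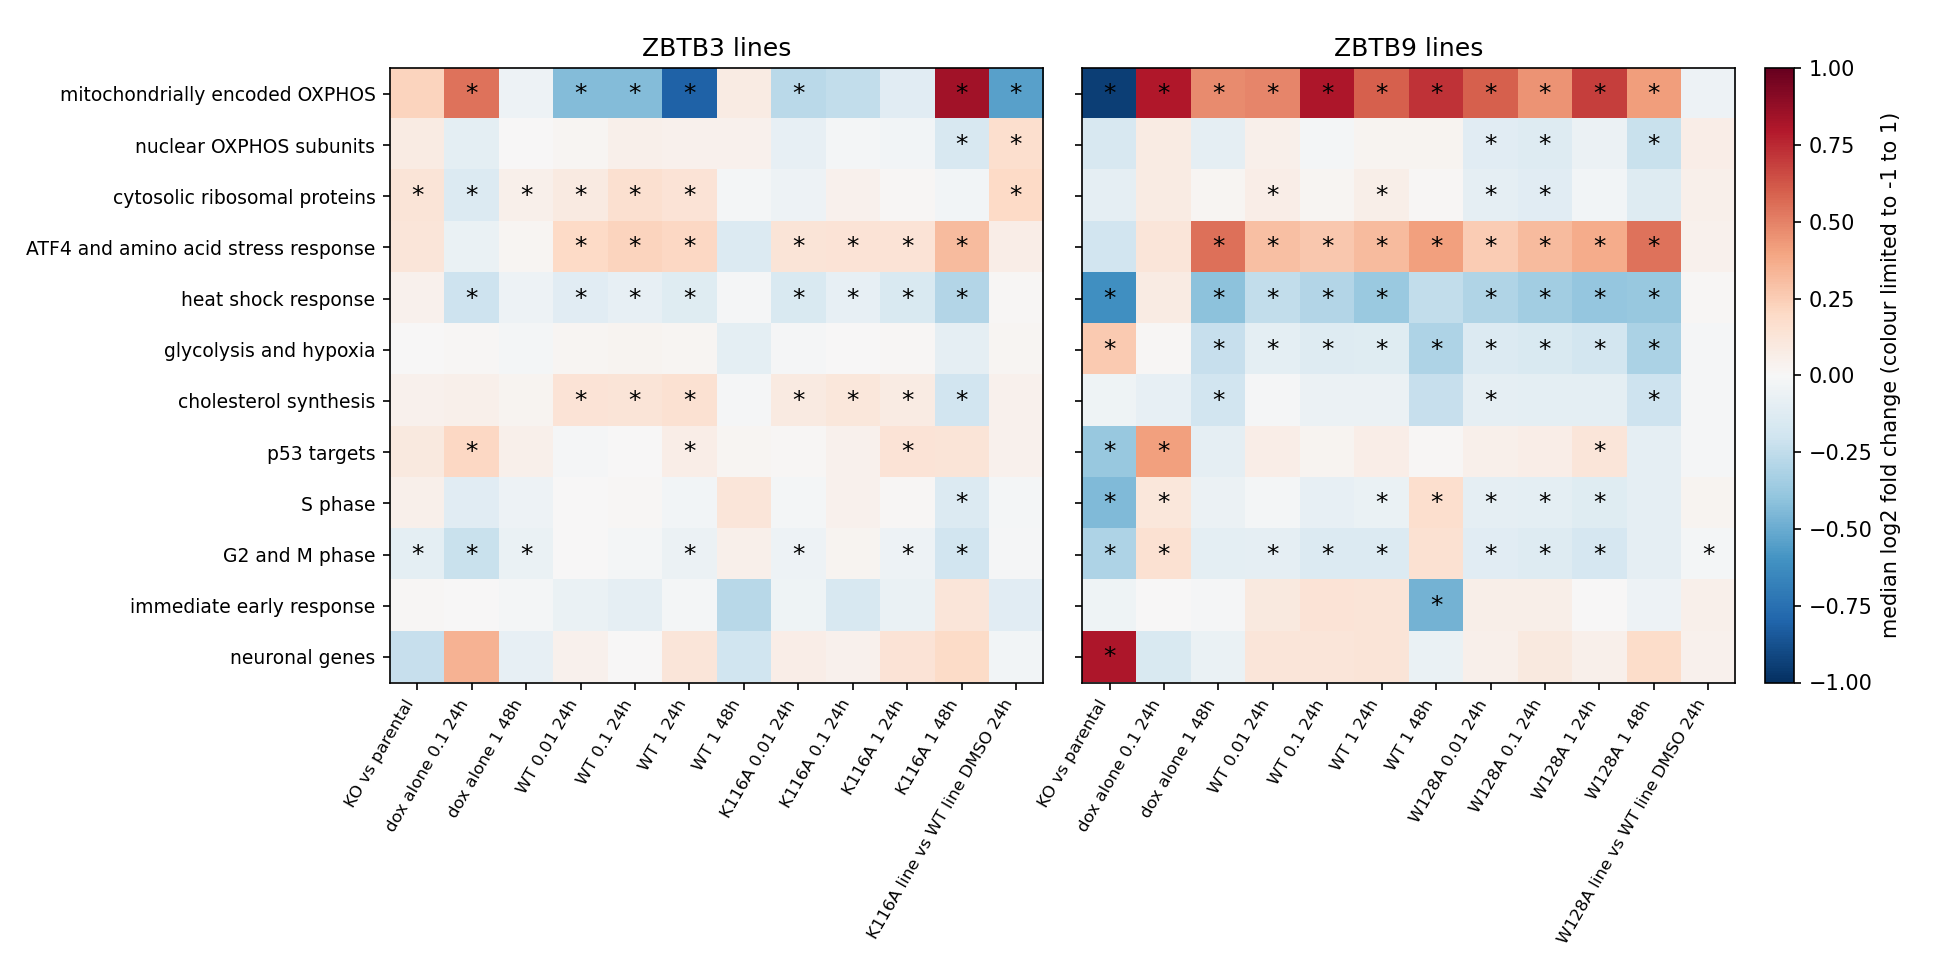
Median log2 fold change of some of the 20 gene lists in each comparison other than the differences between inductions. A star marks a list that passed its test with a preset correlation both before and after GC and length correction, in the same direction. Few of the starred lists held with the correlation estimated from the data.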

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

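These results came up because the WT and mutant inductions differed by a test of the difference itself, an interaction term. The tests in this part were planned, apart from those after GC and length correction and the splits that keep replicate numbers together, which were chosen after the result was seen. At 1 ug/mL for 48 h the WT and K116A inductions of ZBTB3 differed at 7899 genes, SESN2 and HSPE1 among them, and the WT and W128A inductions of ZBTB9 at 4092, CAMK2N2 among them. After GC and length correction the counts were 2630 and 322. Of 40 splits drawn of the 12 libraries 1, the real one, gave as many genes in each case. The highest of the others called 5971 for ZBTB3 and 3863, close to the real count, for ZBTB9. The real count was thus the highest of the splits drawn, but splits not drawn were not counted, so chance was not excluded. The ZBTB9 count also ran from 2024 to 6073 with 1 library left out. After GC and length correction 1 of the same 40 splits, the real one, gave as many again, with 1988 and 239 the highest others. The K116A libraries paired by number at 48 h, and of the 28 splits that keep these pairs in 1 line, as the real one does, the highest other called 1.

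Lists differed as well by camera with a preset correlation, and none of these held with an estimated correlation. For ZBTB3 at 0.01 ug/mL for 24 h they were the ATF4 genes (adjusted p = 0.0202), ribosomal protein genes (1.73e-25, median 0.13) and nuclear OXPHOS genes (1.25e-06), with adjusted p = 0.831, 0.482 and 0.804 with an estimated correlation. At 0.1 ug/mL they were mitochondrially encoded genes (0.00122, median -0.28), ribosomal (1.18e-21, median 0.12) and nuclear OXPHOS genes (8.09e-05), with adjusted p = 0.809 for each with an estimated correlation. At 1 ug/mL for 24 h they were mitochondrially encoded (2.31e-19, median -0.70, 13 of 13 genes lower), ribosomal (1.13e-20, median 0.12) and nuclear OXPHOS genes (1.22e-05), with adjusted p = 0.121, 0.756 and 0.903 with an estimated correlation. Mitochondrial mRNA was already higher with DMSO for 24 h in the WT line (3.02% of counts) than in the K116A line (1.99%). Many ribosomal protein and nuclear OXPHOS genes were already lower in the WT than in the K116A line with DMSO for 24 h. Those DMSO libraries are the controls of the 24 h inductions, so such a difference enters these results too. At 48 h they were mitochondrially encoded (0.0221, median -0.80), ATF4 (5.71e-05), heat shock (0.00495), nuclear OXPHOS (0.0141), S phase (0.00495), G2 and M phase (0.000713), immediate early (0.0215), Wnt (0.0141) and Notch genes (0.0124). After GC and length correction the last 5 of these gave 0.114, 0.555, 0.411, 0.0714 and 0.189. The first 4 kept adjusted p under the threshold after it (7.97e-05, 7.24e-08, 1.91e-07 and 0.00148), and gave adjusted p = 0.624, 0.506, 0.506 and 0.652 with an estimated correlation.

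For ZBTB9 ribosomal and nuclear OXPHOS genes differed at 0.01 (4.44e-19 and 4.4e-11), 0.1 (7.1e-08 and 1.22e-05) and 1 ug/mL (1.92e-05 and 0.00188) for 24 h, with ribosomal medians of 0.16, 0.11 and 0.08 and adjusted p = 0.985, 0.99 and 0.978 with an estimated correlation for both lists. At 48 h nuclear OXPHOS genes differed (0.0294, and adjusted p = 0.905 with an estimated correlation). At 24 h edgeR called 0 single genes of these interactions in either table.

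The 32 counts of genes were also set against other splits of the same libraries. For the 24 h interactions the real count was 0, which all 40 of 40 splits reach by construction, so the splits say nothing of chance there. For ZBTB3 the highest splits called 1248, 1156 and 364 genes at 0.01, 0.1 or 1 ug/mL, which points to a structure of the samples other than the groups. Replicate 3 of the 24 h doxycycline groups lay apart in both lines. For ZBTB9 the highest was 0 at each dose. Every comparison of 3 against 3 libraries has 10 splits, too few for a share under 0.05. There the real counts and highest others were, for ZBTB3, 5068 and 1 (knockout), 4502 and 0 (doxycycline alone, 24 h), 12 and 1 (48 h), 0 and 2, 104 and 0, and 58 and 1 (WT, 24 h doses), 6675 and 0 (WT, 48 h), 0 and 3, 635 and 301, and 142 and 0 (K116A, 24 h doses), 4858 and 1929 (K116A, 48 h) and 448 and 0 (lines with DMSO). For ZBTB9 they were 5987 and 0 (knockout), 309 and 0 (doxycycline alone, 24 h), 649 and 1 (48 h), 0 and 0, 0 and 0, and 1 and 0 (WT, 24 h doses), 3973 and 2528 (WT, 48 h), 0 and 0 at each W128A dose for 24 h, 250 and 0 (W128A, 48 h) and 0 and 0 (lines with DMSO). Where the real count was 0, each of the 10 splits gave as many by construction, and elsewhere 1 split, the real one, did. In the paired comparison, K116A at 48 h, 4 of the 10 splits part all 3 pairs, and the highest of the other 3 called 11 genes. The split that called 1929 keeps pairs together, and the replicate block, whose terms were shared by all groups of the fit, called 5066 genes for the real groups.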

How the results depend on the processing

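Tests with GC and length correction (alone or with a block), with the block within the 24 h doxycycline groups and without their replicate 2 were chosen after the result was seen, and the others were planned. Comparisons are named by dose in ug/mL and time, a hyphen stands for a difference between inductions, and the planned count is in brackets. RLE size factors moved 1 of 32 counts beyond 1.5 times, for ZBTB9 W128A 1 24 h 1 (0). No expression filter moved 6 of 32 counts beyond 1.5 times, for ZBTB3 doxycycline alone 1 48 h 4 (12), WT 1 24 h 38 (58), K116A 0.1 24 h 397 (635), and for ZBTB9 doxycycline alone 0.1 24 h 170 (309), doxycycline alone 1 48 h 334 (649), W128A 1 48 h 122 (250). DESeq2 in place of edgeR moved 18 of 32 counts beyond 1.5 times, for ZBTB3 doxycycline alone 1 48 h 1.2e+02 (12), WT 0.01 24 h 44 (0), WT 0.1 24 h 353 (104), WT 1 24 h 205 (58), K116A 0.01 24 h 1 (0), K116A 0.1 24 h 1002 (635), K116A 1 24 h 408 (142), WT-K116A 1 24 h 1 (0), and for ZBTB9 doxycycline alone 0.1 24 h 667 (309), doxycycline alone 1 48 h 1196 (649), WT 0.01 24 h 2 (0), WT 0.1 24 h 2 (0), WT 1 24 h 3 (1), W128A 0.01 24 h 3 (0), W128A 0.1 24 h 2 (0), W128A 1 24 h 10 (0), W128A 1 48 h 629 (250), WT-W128A 1 24 h 2 (0). A fit of only the groups compared moved 14 of 32 counts beyond 1.5 times, for ZBTB3 doxycycline alone 1 48 h 109 (12), WT 0.1 24 h 180 (104), WT 1 24 h 273 (58), K116A 0.01 24 h 2 (0), K116A 0.1 24 h 0 (635), K116A 1 24 h 6 (142), lines with DMSO 1371 (448), and for ZBTB9 knockout 9953 (5987), doxycycline alone 0.1 24 h 5394 (309), doxycycline alone 1 48 h 2674 (649), WT 1 24 h 0 (1), WT 1 48 h 1 (3973), W128A 1 48 h 2977 (250), lines with DMSO 31 (0). A replicate block moved 5 of 32 counts beyond 1.5 times, for ZBTB3 WT 0.1 24 h 279 (104), WT 1 24 h 137 (58), K116A 1 24 h 394 (142), and for ZBTB9 doxycycline alone 1 48 h 1046 (649), W128A 1 48 h 503 (250). GC and length correction moved 12 of 32 counts beyond 1.5 times, for ZBTB3 doxycycline alone 1 48 h 20 (12), WT 0.1 24 h 201 (104), WT 1 24 h 208 (58), WT 1 48 h 2094 (6675), K116A 0.1 24 h 148 (635), K116A 1 48 h 2455 (4858), WT-K116A 1 48 h 2630 (7899), and for ZBTB9 doxycycline alone 1 48 h 226 (649), WT 1 48 h 585 (3973), W128A 0.1 24 h 1 (0), W128A 1 24 h 2 (0), WT-W128A 1 48 h 322 (4092). The block within the 24 h doxycycline groups moved 12 of 18 counts beyond 1.5 times, for ZBTB3 WT 0.01 24 h 480 (0), WT 0.1 24 h 930 (104), WT 1 24 h 769 (58), K116A 0.01 24 h 663 (0), K116A 0.1 24 h 1622 (635), K116A 1 24 h 1128 (142), and for ZBTB9 WT 0.01 24 h 119 (0), WT 0.1 24 h 766 (0), WT 1 24 h 538 (1), W128A 0.01 24 h 883 (0), W128A 0.1 24 h 693 (0), W128A 1 24 h 1850 (0). Leaving out replicate 2 of those groups moved 3 of 9 counts beyond 1.5 times, for ZBTB9 W128A 0.01 24 h 1 (0), W128A 0.1 24 h 1 (0), W128A 1 24 h 6 (0). GC and length correction with a replicate block moved 1 of 1 counts beyond 1.5 times, for ZBTB3 K116A 1 48 h 2645 (4858). Leaving out 1 library moved 60 of 240 counts beyond 1.5 times, with ranges, for ZBTB3 doxycycline alone 1 48 h 1 to 120, WT 0.01 24 h 0 to 350, WT 0.1 24 h 2 to 536, WT 1 24 h 0 to 424, K116A 0.01 24 h 0 to 500, K116A 0.1 24 h 3 to 994, K116A 1 24 h 1 to 1166, K116A 1 48 h 3237 to 5438, lines with DMSO 1.2e+02 to 336, and for ZBTB9 doxycycline alone 0.1 24 h 60 to 138, doxycycline alone 1 48 h 13 to 1855, WT 1 48 h 837 to 6335, W128A 0.01 24 h 0 to 2, W128A 1 24 h 0 to 1, W128A 1 48 h 13 to 626, WT-W128A 1 48 h 2024 to 6073. Where a group was left with 2 libraries, the spread was pooled over the other groups.

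For gene lists 91 list results for ZBTB3 and 107 for ZBTB9 passed as planned, 2 and 1 with an estimated correlation, and 94 and 37 by fry. Knockout genes that moved back, with no fold requirement, came to 57.1% (WT, 24 h), 56.6% (K116A, 24 h) and 56.3% (K116A, 48 h) for genes lower in the ZBTB3 knockout, no longer past the threshold. For genes lower in the ZBTB9 knockout they came to 27.7% (WT, 24 h), 23% (W128A, 24 h) and 22.9% (W128A, 48 h), against 54.9%, 50.1% and 51.9% of all genes. These lists were now past the threshold by moving further down, not back (adjusted p = 0.139, 0.136 and 0.136 with an estimated correlation). With WT at 48 h 69.9% of genes higher and 76.8% of genes lower in the ZBTB9 knockout moved back (list adjusted p = 5.52e-11 and 2.78e-13, and adjusted p = 0.136 with an estimated correlation for each). GC and length correction gave 54.2% for genes lower in the ZBTB9 knockout with WT at 48 h, no longer past the threshold, and 44.4% for genes higher in it, now in the other direction. Among genes above the median expression the correlations for ZBTB3 were 0.61, 0.73 and 0.86 (WT with K116A, 24 h doses), -0.51 (48 h), -0.42 (K116A 24 h with 48 h), -0.09 and -0.14 (doxycycline alone at 24 h with WT and K116A) and -0.67 and 0.51 (at 48 h). For ZBTB9 they were -0.39 (WT with W128A, 48 h), -0.39 (WT 24 h with 48 h), 0.64 (W128A 24 h with 48 h), -0.36 and -0.07 (doxycycline alone at 24 h with WT and W128A, the second now negative) and -0.58 and 0.86 (at 48 h). GC and length correction gave -0.06 and 0.06 (WT with mutant at 48 h, ZBTB3 and ZBTB9), -0.11 (doxycycline alone with WT at 48 h, ZBTB3, and -0.41 above the median expression, against 0.23 with K116A), 0.03 (doxycycline alone with WT at 24 h, ZBTB9) and 0 (doxycycline alone with WT at 48 h, ZBTB9).

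Of 510 results for single genes, the replicate block left 510 in the same direction and on the same side of the threshold, RLE 507, no filter 408, DESeq2 391, GC and length correction 390 and the fit of only the groups compared 388. Leaving out 1 library left 2471 so and weakened 1019, and FLT3 in the ZBTB3 interaction at 48 h went from 7.49 to -0.68 without K116A DMSO 48 h replicate 3 (8.09 at the highest). Of the ZBTB3 and ZBTB9 levels 33 of 34 stayed within 1 SD when scaled by the total count. Outside the 1 paired comparison, no doxycycline group paired with its DMSO group by number, while the 24 h doxycycline groups of WT and mutant lines did (r from 0.20 to 0.62 for ZBTB3 and 0.63 to 0.93 for ZBTB9). No scaling moved the median of all genes by more than 0.05. The cause of the shifts between fits was not tested. Depth limits what can be said of genes near 1 CPM, such as PRR22.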

Other observations

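Of the tests in this part, those of GC content and of exchanged labels for the 48 h inductions and that of RN7SL1 and RN7SL2 in the transgene lines were chosen after the result was seen. At 48 h the WT and mutant inductions moved genes above the median expression in opposite directions, with r of -0.51 for ZBTB3 and -0.39 for ZBTB9 (-0.22 and -0.09 over all genes), which the number of counts as such does not account for, as thinning every library to 7.59 and 12.3 M counts left r at -0.50 and -0.39. A trend with GC content that differed between libraries may account for much of it. After GC correction r became -0.08 and 0.27, and 2406 and 235 interaction calls were left. The ZBTB3 interactions of HSPE1 and SESN2 were 1.39 ± 0.15 and -1.61 ± 0.20 before and 1.3 and -1.02 after GC and length correction, both still called. With that correction 447 ZBTB3 genes stayed opposite, against 52 and 87 alike where chance gives 56.4 and 106. The correction takes out only a smooth trend per library. What it left does not settle whether GC content or library preparation was the whole cause. The slope on GC (log2 per 10 points) averaged 0.141 (SD 0.035) in WT DMSO and -0.149 (0.031) in WT doxycycline libraries of ZBTB3 at 48 h against -0.105 (0.039) and 0.104 (0.09) in the K116A line, and 0.141 (0.24, from -0.119 to 0.354) and -0.179 (0.021) against -0.218 (0.029) and -0.036 (0.11) for ZBTB9, with the WT DMSO group the least uniform. Library totals went opposite ways in the lines as well, which thinning leaves untested as a mark of how the libraries were made. In the ZBTB3 WT line they were 18.5 to 23.6 M with DMSO and 11 to 11.9 M with doxycycline. The K116A line had 7.6 to 12 M and 13.5 to 19.1 M. For ZBTB9 the totals were 18 to 33.8 M and 12.6 to 13.3 M with WT, and 12.3 to 19.3 M and 16.6 to 23.2 M with W128A. Exchanged labels were excluded for the ZBTB9 WT line, where the lowest ZBTB9 level with doxycycline stood a log2 of 1.11 above the highest with DMSO, and stayed open for ZBTB3, whose counts gave no clear sign of the transgene (r of -0.08 with K116A after GC correction). The ZBTB3 WT responses to 1 ug/mL at 24 h and 48 h share no library. After GC and length correction 22 genes were higher and 39 lower in both (4.79 and 8.94 by chance), and 12 were opposite, which runs the labelled way. Their correlation over all genes was 0.05, and the 24 h calls moved with single libraries, so this did not settle the labels. After GC and length correction the ZBTB3 WT line at 48 h still ran against knockout cells with doxycycline but no transgene (r of -0.41 above the median expression, against 0.23 for K116A), which exchanged labels or an effect of WT ZBTB3 would both give, so what the K116A mutation did to SESN2 or HSPE1 stays open.

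Replicate 2 of all 6 ZBTB9 24 h doxycycline groups lay apart from replicates 1 and 3, with a gap of 55.7% of the range of the first principal component. After GC correction the gap was 56.8%, which argues against a GC trend, and 25% was the highest share of markers of another cell type higher by a log2 of 1 or more (1 of 4 detected fibroblast markers), under the bound set in advance but, with few markers detected and 3 of those 4 higher in all 6 groups, weak evidence that leaves fibroblasts open. NEAT1 was higher by 2.62 (SD 0.25 over 6 groups), MALAT1 by 2.02 (SD 0.27, 84.1 to 113 CPM against 18.5 to 31.7), SLC7A11 by 1.84 (0.14) and DDIT4 by 1.72 (0.16), while HSPA1B, a near copy of HSPA1A, changed by -1.85 (0.20) and HSPA8 by -1.72 (0.11). Of the 6790 genes over 5 log2 CPM 72 were higher and 17 lower by at least 1. A shared difference in handling or harvest of replicate 2 may be the source, which the labels do not record, and apart from cells of another type no biological explanation was tested. It widens the spread at 24 h, and a block within those groups raised the WT calls at 0.1 ug/mL from 0 to 766, while leaving replicate 2 out of them gave 0.

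The list medians in replicate 2 against the others, with members higher and lower in all 6 groups, were 0.84 for mitochondrially encoded genes (11 and 0 of 13), 0.47 for ATF4 (27 and 2 of 31), -0.86 for heat shock (0 and 16 of 17), -0.47 for cholesterol (1 and 20 of 23), -0.30 for S phase (2 and 31 of 40), -0.29 for G2 and M phase (2 and 37 of 53), -0.31 for ribosomal (0 and 63 of 76), -0.39 for nuclear OXPHOS (1 and 41 of 50), -0.17 for unfolded protein (6 and 14 of 22) and -0.28 for glycolysis (4 and 19 of 29). They were 0.20 for p53 (13 and 5 of 23), 0.32 for interferon (9 and 4 of 22), 0.08 for immediate early (7 and 7 of 28), 0.07 for Wnt (5 and 2 of 15), 0.20 for TGF-beta (11 and 5 of 23), 0.45 for Notch (9 and 5 of 16), 0.17 for germline (5 and 2 of 15), 0.40 for neuronal (12 and 8 of 34), -0.01 for the ZBTB family (17 and 12 of 46) and -0.09 for corepressors (5 and 11 of 23). Epithelial (5 detected), fibroblast (4) and blood markers (4) had medians of 0.35 (1 and 1), 0.66 (3 and 0) and -0.19 (1 and 0), and 0 liver markers were detected.

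RN7SL1 and RN7SL2 were about as high in the treated knockout libraries of both genes at 0.1 ug/mL for 24 h (252 and 256 CPM for ZBTB3, 264 and 282 for ZBTB9). A response to doxycycline as such is argued against, since their highest log2 fold change at that dose and time in the transgene lines was 0.15 for ZBTB3 and 0.27 for ZBTB9. A difference in library preparation may be the source, since these short RNAs depend on how RNA is selected, but the labels name no batch and this was not tested. The sample sheets give the control libraries 0 h, so a difference in time or treatment other than doxycycline stays open too. The p53 targets that rose in the same comparisons, CDKN1A among them, share that limit.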
